A study of Homo sapiens with 18 samples.

How the data were processed

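RNA was measured by sequencing in MCF7 cells, a human estrogen receptor-positive breast adenocarcinoma line, after transfection with a control siRNA (siControl, 3 samples) or an siRNA against the long noncoding RNA HOTAIRM1 (siHOTAIRM1, 3 samples). The series also holds 12 ChIP-seq samples of estrogen receptor alpha, FOXA1 and input DNA from cells with a control or a HOTAIRM1 shRNA, without or with 10 nM estradiol for 1 h, 1 sample per condition. They were not analysed here. Groups were taken from the sample titles, which number the replicates 1 to 3 in each group. The treatment tag of the siControl samples names a control vector, not an siRNA, and that of the siHOTAIRM1 samples a knockdown of HOTAIRM1, so how the controls were made is not certain. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Nor do they say whether the RNA-seq cells were deprived of hormone or given estradiol.

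The authors deposited 1 table of 22900 genes with an Ensembl identifier, a symbol, a gene type, an FPKM value per sample (fragments scaled to gene length and to the sample's total, with 2 decimals) and their own log2 fold change, p-value and FDR for the same comparison. The genome build hg19 and the tools CASAVA 1.8.2, Bowtie 1.1.0 and MACS 1.4.2 are named in the submitters' processing notes, with no role. The quantifier of the FPKM, the gene annotation, the strand setting and the test behind the deposited p-value are not given in the sources used here, and the library protocol in the labels describes ChIP-seq only. Without a known strand setting, reads of overlapping or antisense genes, such as HOTAIRM1 and HOXA1, cannot be told apart with certainty. The same holds for near-identical copies such as the histone genes. FPKM are not counts, so no count test was run. The low values gave the relative depth, which lay within -0.3 to 4.2% of siControl replicate 1, but whole reads were not recovered and the total depth is unknown. The FPKM summed to between 671555 and 725036 per sample, and between 12332 and 12572 genes had an FPKM of at least 1.

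Fold changes and tests were computed here from the FPKM, with R 4.3.3 and limma 3.58.1. The values were transformed to log2(FPKM + 1), which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 6 samples were kept, which left 12478. Groups were compared with limma's two-sided moderated test with a variance trend, without a block, and the p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. HOTAIRM1 and the genes of the HOXA region were also fitted without the expression filter and tested with a two-sided exact permutation test, whose smallest possible p is 0.1 with 3 samples against 3. Printed means and SDs are of FPKM over the 3 samples of a group, and a fold printed beside them is the ratio of those means.

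Before the data were examined, 22 gene lists were fixed: estrogen-induced genes, estrogen-repressed genes, luminal regulators and ER cofactors, the HOXA cluster, G1/S, G2/M, interferon response, p53 targets, integrated stress and unfolded protein response, heat shock, immediate early genes, NF-kB targets, cholesterol biosynthesis, hypoxia and glycolysis, epithelial adhesion and keratins, mesenchymal and basal markers, retinoic acid response, Polycomb and trithorax genes, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, and markers of fibroblast, blood and endothelial cells. A list needed 5 tested members. The mitochondrially encoded list had 0 genes in the table and was not tested, which left 21. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists, and again with an estimated correlation and with fry. The rule for named genes was fixed at the same time. It takes HOTAIRM1 and the HOXA cluster genes, then ESR1, FOXA1 and GATA3. It adds the 10 largest rises and 10 largest falls among called genes with a symbol, at least 5 FPKM in the higher group and no overlap between groups, and up to 4 members of each list with the smallest p. Genes named outside it are said to be so.

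The test was tried on simulated values of this comparison with 12478 genes, 100 of them changed by 0.5, 100 by 1 and a list of 30 by 0.2 on the log2 scale. It recovered 57% of those changed by 0.5 and 93% of those changed by 1, called 1 of the 30, and 4.4% of its 158 calls were false. The simulated noise was independent between genes and between samples, and few genes were changed, so these shares need not hold for the real samples. The changed genes and the list were drawn only from genes with a mean log2(FPKM + 1) above 2, so the shares do not cover lower genes. Replicates 2 and 3 of siHOTAIRM1 lay close to each other. The SD of their log2 difference over 2202 genes with a mean of at least 50 FPKM was 0.073, against 0.126 to 0.191 for the other pairs of a group. It was 0.074 over 1094 genes of 50 to 100 FPKM, 0.065 over 918 of 100 to 500 and 0.099 over 190 of at least 500, where siControl replicates 2 and 3 were closer (0.093). Without counts it could not be set against counting error, and the samples were counted separately, as the titles name them. Averaging them into 1 sample was added as an alternative after seeing the data. The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, median-ratio scaling, quantile normalization, a robust prior, no variance trend, the replicate number as a block, each sample left out in turn, minimum fold changes, and the other set tests. A count test was planned only for recovered reads and was not run.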

Results

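The comparison asks what changes in MCF7 RNA when HOTAIRM1, a long noncoding RNA, is knocked down, and in particular whether estrogen-responsive genes move, since the series concerns estrogen receptor activity. FPKM of 3 siControl and 3 siHOTAIRM1 samples were compared. No RNA-seq group had another siRNA against HOTAIRM1 or a rescue. Changes through the loss of HOTAIRM1 therefore cannot be told apart from other effects of the siRNA. The first principal component held 56.2% of the variance and separated the groups, while siHOTAIRM1 replicate 1 stood apart on the second (18.6, against -10.5 to 6.7 for the other 5 samples). KRT8, a luminal keratin outside the naming rule and chosen after its values were seen, had the highest FPKM in each of the 6 samples.

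HOTAIRM1 (ENSG00000233429) was reduced in each of the 3 knockdown samples. It lies between HOXA1 and HOXA2 on chromosome 7 in the RefSeq annotation of GRCh38.p14, which gives the gene order only, because the authors' build was hg19. Its FPKM was 4.74, 5.02 and 3.99 in siControl and 0.40, 1.14 and 1.03 in siHOTAIRM1, or 4.58 ± 0.533 against 0.857 ± 0.399 (SD, n = 3 each), 5.35-fold lower. In the fit without an expression filter the log2 fold change was -1.61 (SE 0.19, limma adjusted p = 0.0062), and the exact permutation p was 0.1, the smallest that 3 against 3 can give. HOXA5, HOXA10 and HOXA4, homeobox transcription factor genes of the same region, fell as well. In the fit with the filter, HOXA5 was 3.94 ± 0.626 FPKM in siControl and 1.83 ± 0.58 in siHOTAIRM1, 2.16-fold lower (adjusted p = 0.00762, or 0.0444 without the filter), and HOXA10 was 5.83 ± 0.398 and 3.83 ± 0.176, 1.52-fold lower (adjusted p = 0.00521, or 0.0195 without the filter). HOXA4 was 5.44 ± 0.98 and 3.57 ± 0.291 (adjusted p = 0.0236), but lost the call without the filter (adjusted p = 0.0817), and its adjusted p rose to 0.0844, 0.0781 and 0.0729 without siControl replicate 1, siControl replicate 2 and siHOTAIRM1 replicate 2. HOXA7 was 1.51 ± 0.0723 and 1.04 ± 0.284 FPKM and did not pass the test (adjusted p = 0.115), nor did SKAP2, a neighbour outside the HOX genes, at 7.6 ± 1.19 and 8.75 ± 1.58 (adjusted p = 0.4). The other 13 of 19 genes of the region averaged under 1 FPKM, HOXA1 among them (0.437 ± 0.0666 and 0.383 ± 0.0987). HOXA13, also among them, lay the other way, at 0.173 ± 0.0321 and 0.297 ± 0.0404 FPKM without overlap, and did not pass the test without the filter (adjusted p = 0.0804), while its log2 fold change in the authors' deposited table was 0.79 (FDR 0.0272). Of the 6 tested members of the HOXA list, HOTAIRM1 included, 4 fell and 0 rose (0 higher and 5 lower when adjusted over the list alone). The list was lower by camera (adjusted p = 0.0276), with adjusted p = 0.205 with an estimated correlation and 0.196 without the expression filter, and its 5 members without HOTAIRM1 had a median log2 fold change of -0.48 (unadjusted camera p = 0.0385, or 0.102 with an estimated correlation).

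**Figure D1:**
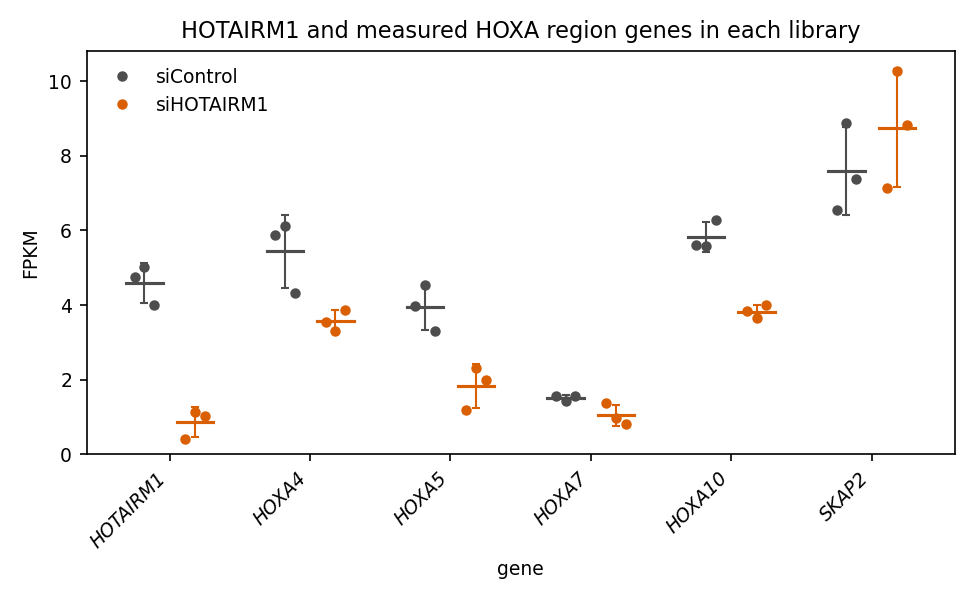
FPKM (linear axis) of HOTAIRM1 and the 5 other genes of the HOXA region with a mean of at least 1 FPKM. Points are single libraries, horizontal lines group means and bars SDs (n = 3). The siHOTAIRM1 samples lay between 0.40 and 1.14 FPKM for HOTAIRM1, all below the siControl samples, while SKAP2 overlapped between the groups.

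Across the transcriptome, 1412 genes were higher and 1733 lower after knockdown, together 25.2% of the 12478 tested, and most changes were small. A log2 fold change of at least 1 was reached by 80 of the higher and 36 of the lower genes. The groups did not overlap in 5169 genes, 41.4% of those tested, where chance gives 10%. The largest rises were in TMCO1, an endoplasmic reticulum calcium channel (11.4 ± 1 FPKM in siControl, 47.7 ± 8.27 in siHOTAIRM1, log2 fold change 1.96, SE 0.12, adjusted p = 3.7e-05), and SCN1B, a sodium channel beta subunit (8.16 ± 0.655 and 34.3 ± 1.12, 4.2-fold higher). MDK, which encodes the growth factor midkine, rose from 121 ± 7.26 to 399 ± 17.9 FPKM and was the most abundant gene among the 10 largest rises. STC1, CCNG1, STRADB, PLA2G16, CAPN2, MALL and RMI2 completed these, with folds of 2.7 to 3.84. By FPKM, the largest fall on the log2 scale was in DNAJC27-AS1, an antisense RNA (7.01 ± 1.88 and 1.08 ± 0.251 FPKM, 6.49-fold lower, adjusted p = 0.000142). Its log2 fold change in the authors' deposited table was smaller, -1.05 (FDR 0.0124), against -2.13 to -1.45 there for the 9 others of the 10 largest falls. NELL2, a secreted glycoprotein (10.2 ± 0.206 and 2.58 ± 0.183), and ASCL1, a neuroendocrine transcription factor (26.5 ± 0.861 and 8.27 ± 0.114), fell by 1.65 and 1.57 on the log2 scale. SBDS, a ribosome maturation factor, fell from 65.4 ± 3.44 to 23.6 ± 4.92 FPKM, and EMC10, a subunit of a membrane protein complex of the endoplasmic reticulum, from 145 ± 10.4 to 52.6 ± 5.87. ACSS1, CSTA and the interferon-response genes IFI27, IFI6 and IRF9 made up the rest of the 10 largest falls.

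**Figure D2:**
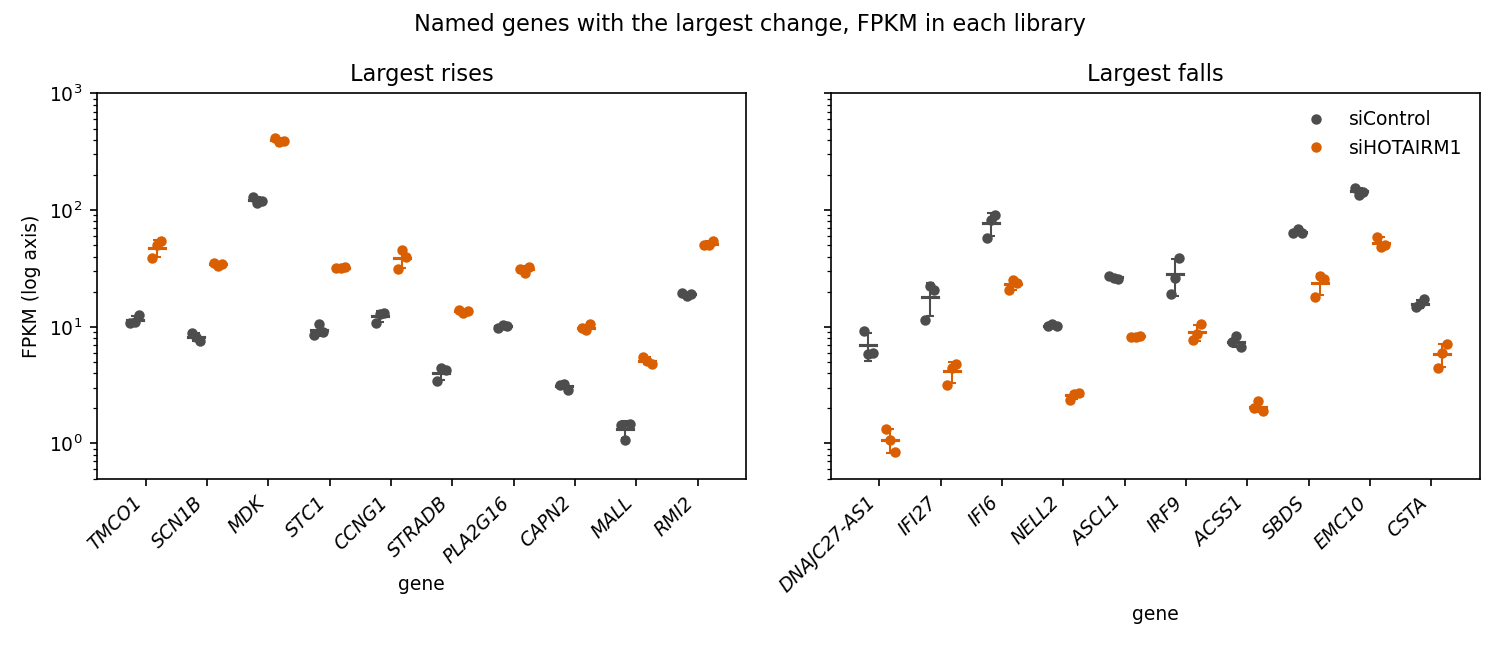
FPKM on a log axis of the 10 genes with the largest rise (left) and the 10 with the largest fall (right) among called genes of at least 5 FPKM in the higher group. Points are single libraries, lines group means and bars SDs (n = 3). The groups are apart in each gene by construction of the rule, and MDK had the highest mean, 399 FPKM in siHOTAIRM1.

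Estrogen-induced genes moved upward on balance, by a small amount. Of 56 tested members 19 rose, 4 fell and 33 did not pass the test (21 higher and 6 lower when adjusted over the list alone), and the median log2 fold change was 0.09, or 0.14 after quantile normalization. CA12, a carbonic anhydrase, rose from 48.6 ± 3.98 to 117 ± 2.81 FPKM (2.41-fold, adjusted p = 2.67e-05), and KRT13 from 4.44 ± 0.546 to 13 ± 1.51 (2.93-fold). SIAH2, a ubiquitin ligase, fell from 72.3 ± 2.06 to 41.9 ± 2.92 and CALCR, the calcitonin receptor, from 19.3 ± 1.85 to 7.85 ± 1.43. The classical estrogen receptor targets GREB1, TFF1 and PGR, picked out after their values were seen, did not pass the test, with log2 fold changes of 0.09, 0.06 and -0.06 (adjusted p = 0.357, 0.684 and 0.6). For PGR the log2 fold change in the authors' deposited table had the other sign, 0.261 (FDR 0.0649). Camera called the list higher (adjusted p = 0.0019), with adjusted p = 0.111 with an estimated correlation, and 2 other splits of the 6 samples gave as small a camera p. Of 18 estrogen-repressed genes, 8 fell and 3 rose (9 lower and 3 higher when adjusted over the list alone). Camera did not call the list (adjusted p = 0.14), while fry did (adjusted p = 0.0119). CYP1A1, a cytochrome P450 enzyme, fell from 4.81 ± 0.907 to 1.62 ± 0.154 FPKM and TGFB3 from 7.28 ± 0.245 to 4.01 ± 0.172, while BIK, which promotes apoptosis, rose from 2.34 ± 0.0808 to 4.97 ± 0.594.

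The receptor itself and its pioneer factor differed little. ESR1, which encodes estrogen receptor alpha, was 52.5 ± 3.41 FPKM in siControl and 53.9 ± 2.26 in siHOTAIRM1 (log2 fold change 0.04, SE 0.07, adjusted p = 0.739). FOXA1 was 138 ± 3.31 and 123 ± 1.95 (log2 fold change -0.16, adjusted p = 0.0693). GATA3, a luminal transcription factor, fell from 513 ± 12.8 to 421 ± 2.89 (log2 fold change -0.28, adjusted p = 0.00686). Among 28 luminal regulators and ER cofactors 2 rose and 2 fell (1 higher and 2 lower when adjusted over the list alone), and camera did not call the list (adjusted p = 0.938). The corepressor NCOR2 rose from 41.4 ± 2.81 to 59.1 ± 1.99. MLLT4, which encodes the cell-junction protein afadin, rose and the coactivator NCOA3 fell from 193 ± 19.9 to 156 ± 7.99. NCOA3 lost its call without siControl replicate 2, siControl replicate 3 or siHOTAIRM1 replicate 3 (adjusted p = 0.0795, 0.0743 and 0.0736). MLLT4 kept its call only without siControl replicate 2, with adjusted p = 0.109 and 0.144 without siControl replicates 1 and 3 and 0.0534, 0.102 and 0.129 without siHOTAIRM1 replicates 1, 2 and 3.

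Interferon-response genes were lower after knockdown. Of 25 tested members 13 fell and 0 rose (18 lower and 0 higher when adjusted over the list alone), all 25 had a log2 fold change below 0, and the median was -0.47. Over all 41 members, without the expression filter, the median was -0.25. IFI6 fell from 76.9 ± 17 to 23.1 ± 2.32 FPKM (3.33-fold, adjusted p = 0.000165), IFI27 from 18.1 ± 5.83 to 4.14 ± 0.86 (4.37-fold), IRF7 from 15.4 ± 1.22 to 7.89 ± 0.843 and IFITM1 from 33.7 ± 2.69 to 20.6 ± 1.18. IRF9, a subunit of the complex that carries interferon signals to DNA, fell from 28.3 ± 10.1 to 8.96 ± 1.42. Camera called the list lower (adjusted p = 1.92e-07), with adjusted p = 0.307 with an estimated correlation. Its mean log2 value was 3.16, 3.35 and 3.49 in the siControl samples and 2.68, 2.77 and 2.80 in the siHOTAIRM1 samples.

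Replication-dependent histone genes, which package newly made DNA, fell together. Of 22 tested members 16 fell and 0 rose (17 lower and 0 higher when adjusted over the list alone), with a median log2 fold change of -0.42. HIST1H1C fell from 155 ± 8.79 to 87.9 ± 2.65 FPKM (1.77-fold, adjusted p = 9.72e-05), HIST1H3D from 14.1 ± 1.46 to 7.26 ± 0.18, HIST1H2AE from 47.1 ± 3.27 to 28.7 ± 1.39 and HIST2H2BE from 114 ± 8.01 to 74.3 ± 3.15. Camera called the list lower (adjusted p = 1.2e-07), with adjusted p = 0.0639 with an estimated correlation. How reads were divided among these near-identical genes is not known. Other cell-cycle genes did not move as groups. Of 30 G1/S genes 3 rose and 2 fell (camera adjusted p = 0.635, 2 higher and 2 lower when adjusted over the list alone): CDC25A, a phosphatase, fell from 14.7 ± 0.862 to 7.88 ± 0.404 and TK1 from 193 ± 15.7 to 146 ± 12.6, while GINS1 rose from 11 ± 0.868 to 19.7 ± 0.724 and GINS2 from 34.9 ± 1.17 to 44.2 ± 2.44. The third to rise was CDC6, outside the naming rule and chosen after its value was seen, which lost the call in each fit without 1 library except that without siHOTAIRM1 replicate 3 (adjusted p of up to 0.144). Of 30 G2/M genes 3 rose and 1 fell (adjusted p = 0.619, 1 higher and 0 lower when adjusted over the list alone). The mitotic kinase gene PLK1 rose from 65.7 ± 4.46 to 93 ± 7.31. ECT2, HMMR and BIRC5 made up the other calls and each lost it in several fits without 1 library, with adjusted p of up to 0.127, 0.17 and 0.143.

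Of 22 genes of the integrated stress and unfolded protein response 8 rose and 3 fell (10 higher and 3 lower when adjusted over the list alone), and camera called the list higher (adjusted p = 0.0276, and adjusted p = 0.205 with an estimated correlation). MANF, a chaperone-like protein of the endoplasmic reticulum, rose from 32.7 ± 0.806 to 70 ± 2.2 FPKM (adjusted p = 2.67e-05), HSPA5 from 149 ± 5.95 to 208 ± 14.7 and DDIT4 from 40.3 ± 1.87 to 63.8 ± 2.75. PPP1R15A, a phosphatase subunit of the same response, fell from 24.5 ± 1.35 to 17 ± 0.42. The other falls were VLDLR and DDIT3 (log2 fold change -0.36 and -0.28), outside the naming rule and chosen after their values were seen. The list joins the integrated stress and the unfolded protein response, and its call does not tell them apart. Of 23 cholesterol biosynthesis genes 2 rose and 0 fell (2 higher and 0 lower when adjusted over the list alone), LDLR from 37.2 ± 2.42 to 52.7 ± 3.1 and ACAT2 from 44.6 ± 4.1 to 56.8 ± 1.27, and camera called the list higher (adjusted p = 0.0276, and adjusted p = 0.205 with an estimated correlation). LDLR encodes the LDL receptor, which takes up cholesterol and does not make it. Without siControl replicate 2 neither list was called (adjusted p = 0.0637 for each).

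Of 7 tested mesenchymal and basal markers 4 rose and 1 fell (4 higher and 1 lower when adjusted over the list alone). The list had 21 genes in the table, and the others averaged under 1 FPKM. Its median log2 fold change was 0.37 over the tested members. Without the expression filter it was 0.04 over all 21, where camera also called the list higher (adjusted p = 0.0166). The adhesion receptor CD44 rose from 21.7 ± 0.523 to 30.3 ± 1.2, FOXC1 from 3.68 ± 0.248 to 5.82 ± 0.484 and ITGA6 from 2.82 ± 0.481 to 5 ± 0.663. KRT17, outside the naming rule and chosen after its value was seen, was 0.78 ± 0.0361 and 1.3 ± 0.2. Its log2 fold change of 0.37 (adjusted p = 0.0463) stayed above 0 in the 6 fits without 1 library, where the call was lost (adjusted p of 0.0816 to 0.117). SNAI1, which represses epithelial genes, fell from 3.26 ± 0.666 to 2.13 ± 0.185, with adjusted p of 0.133, 0.103, 0.0902 and 0.134 without siControl replicate 1, siControl replicate 3, siHOTAIRM1 replicate 2 and siHOTAIRM1 replicate 3. Camera called the list higher (adjusted p = 0.0345, and adjusted p = 0.408 with an estimated correlation), though not without siControl replicate 2 (adjusted p = 0.0922), without siHOTAIRM1 replicate 1 (adjusted p = 0.12) or after quantile normalization (adjusted p = 0.0634). Of 22 epithelial adhesion and keratin genes 4 rose and 2 fell (adjusted p = 0.407, 5 higher and 2 lower when adjusted over the list alone). CDH1, which encodes E-cadherin, rose from 199 ± 9.62 to 255 ± 7.12 and TJP1 from 17.8 ± 1.65 to 24.5 ± 1.04. ESRP1 rose, with its call lost in several fits without 1 library (adjusted p of up to 0.0943). RAB25 fell, with its call lost without siHOTAIRM1 replicate 3 (adjusted p = 0.0628). Of 6 tested markers of fibroblast, blood and endothelial cells 1 fell, HBA1 (10.1 ± 1.85 and 6.77 ± 0.986), which lost the call without siControl replicate 1, siControl replicate 2 or siHOTAIRM1 replicate 3 (adjusted p = 0.102, 0.0886 and 0.102), and the list was not called (adjusted p = 0.635, 0 higher and 1 lower when adjusted over the list alone).

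Ribosomal protein genes had a median log2 fold change of -0.16, which was -0.07 without siControl replicate 3 and -0.03 after quantile normalization. Their mean log2 value overlapped between the groups, at 10.75, 10.69 and 10.87 in siControl and 10.71, 10.61 and 10.66 in siHOTAIRM1. Of 38 members 1 rose and 2 fell (1 higher and 0 lower when adjusted over the list alone). RPLP2 rose from 615 ± 55 to 869 ± 47 FPKM. RPL38 and RPL15 fell, with calls lost in several fits without 1 library (adjusted p of up to 0.122 and 0.123). Camera called the list lower (adjusted p = 0.0441, and adjusted p = 0.775 with an estimated correlation), but not without siControl replicate 3 (adjusted p = 0.512), siHOTAIRM1 replicate 2 (adjusted p = 0.264) or siHOTAIRM1 replicate 3 (adjusted p = 0.0922), after quantile normalization (adjusted p = 0.244) or median-ratio scaling (adjusted p = 0.164), with a filter at 5 FPKM (adjusted p = 0.127), without the variance trend (adjusted p = 0.0507) or with siHOTAIRM1 replicates 2 and 3 averaged (adjusted p = 0.172), an alternative chosen after seeing the data.

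The remaining lists were not called by camera. Of 28 p53 targets 5 rose and 9 fell (adjusted p = 0.414, 5 higher and 10 lower when adjusted over the list alone), with CCNG1 up from 12.3 ± 1.3 to 39.2 ± 7.25 FPKM, TP53INP1 up from 4.26 ± 0.714 to 8.19 ± 0.358 and GDF15 down from 267 ± 12.7 to 183 ± 12.1. Of 15 immediate early genes 3 rose and 4 fell (adjusted p = 0.414, 3 higher and 5 lower when adjusted over the list alone), with EGR1 down from 5.44 ± 0.204 to 2.36 ± 0.246. Of 11 retinoic acid response genes 3 rose and 1 fell (adjusted p = 0.085, 3 higher and 1 lower when adjusted over the list alone), and the list was called without siControl replicate 1 (adjusted p = 0.0379). TGM2, a transglutaminase, rose from 1.83 ± 0.0611 to 6.34 ± 0.304 and STRA6, a receptor for retinol-binding protein, from 1.8 ± 0.147 to 3.46 ± 0.392. ALDH1A3 rose and RARG fell, with calls lost in several fits without 1 library (adjusted p of up to 0.151 and 0.0755). Of 21 hypoxia and glycolysis genes 3 rose and 4 fell (adjusted p = 0.938, 3 higher and 5 lower when adjusted over the list alone), with PFKFB3 up from 8.82 ± 0.779 to 17 ± 0.348 and HK2 down from 26.3 ± 2.85 to 18.1 ± 0.632. Of 25 Polycomb and trithorax genes 3 rose and 4 fell (adjusted p = 0.876, 3 higher and 4 lower when adjusted over the list alone), with JARID2 up from 15.9 ± 0.942 to 23.8 ± 0.949 and CBX8 down from 18.2 ± 2.75 to 12 ± 0.651. Of 7 NF-kB targets 1 rose and 1 fell (adjusted p = 0.407, 2 higher and 1 lower when adjusted over the list alone), and of 15 heat shock genes 1 rose and 0 fell (adjusted p = 0.636, 0 higher and 0 lower when adjusted over the list alone). These calls were NFKBIA, NFKBIE and HSPB1. Each was lost in several fits without 1 library, with adjusted p of up to 0.105, 0.0546 and 0.103.

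**Figure D3:**
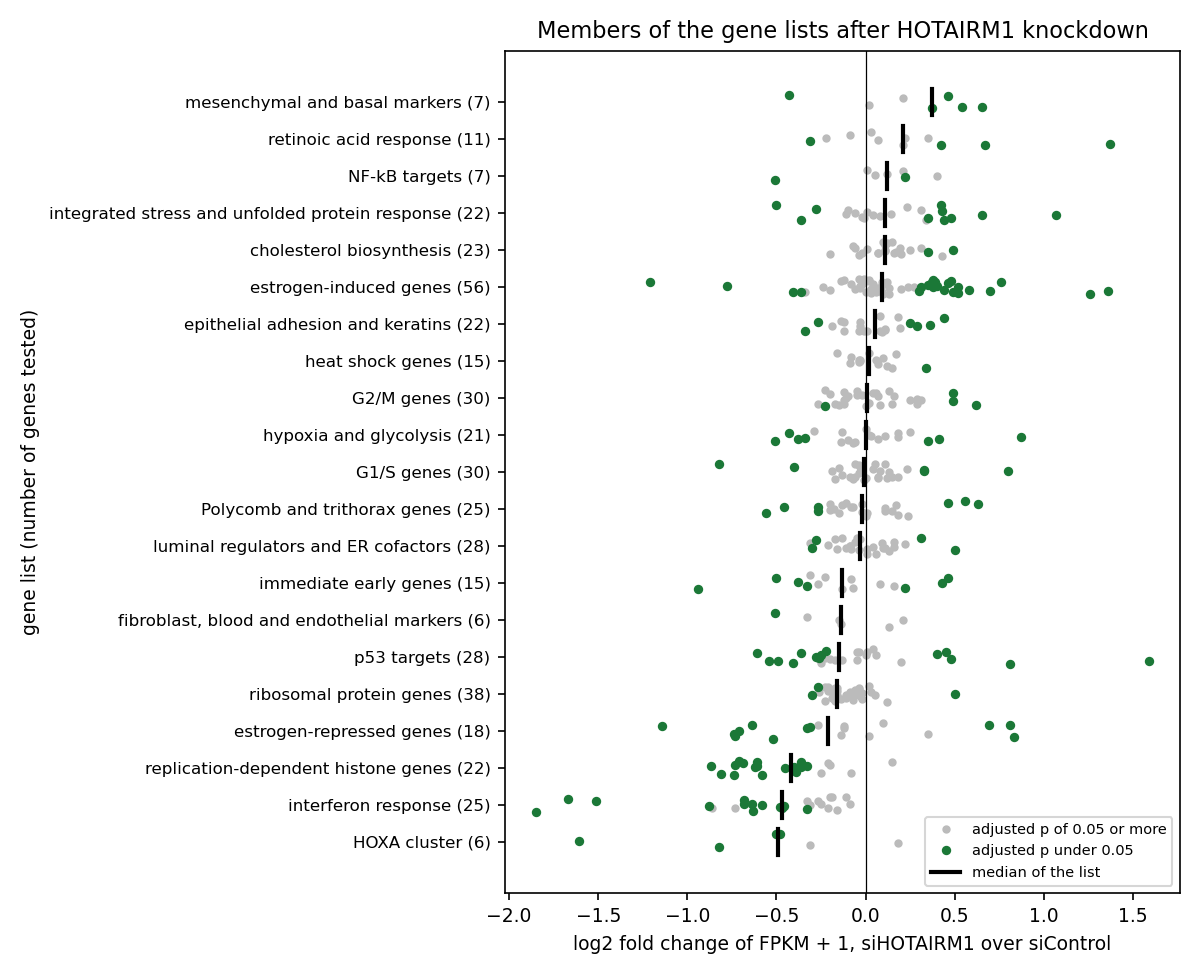
Log2 fold change of FPKM + 1, siHOTAIRM1 over siControl, of each tested member of the 21 lists, ordered by median. Green points passed an adjusted p under 0.05, grey points did not, and black bars are list medians (-0.47 for the interferon response and -0.42 for the histone genes). The vertical spread within a list carries no information.

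The counts rest on limma's test, which called 931 higher and 1112 lower genes without siControl replicate 3, 891 and 982 without siHOTAIRM1 replicate 3, and 1128 lower genes without siHOTAIRM1 replicate 2. None of the 8 list calls held with an estimated correlation. The estimate was 0.28 for the interferon list, 0.16 for the mesenchymal and basal markers and 0.46 for the ribosomal protein genes. For the other called lists it was -0.08 to -0.01, below the preset 0.01, so a higher correlation did not end those calls. In the authors' deposited table, a total of 3858 genes had an FDR under 0.05, 1955 of them higher, and of its 3355 such genes among those tested here 2817 were called here as well, all with the same direction of change.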

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

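Averaging siHOTAIRM1 replicates 2 and 3 into 1 sample was chosen after seeing the data, and the other settings before. The fold change and call of HOTAIRM1 kept their side of the threshold in each of 15 settings that changed its fit (log2 fold change -2.39 to -1.42, adjusted p = 0.00035 to 0.0347). The genes called higher numbered 891 to 1728 and those lower 982 to 1934 with 1 library left out, the lower ends more than 1.5 times below the full counts, with fewer samples. Averaging siHOTAIRM1 replicates 2 and 3 left 965 higher and 1064 lower genes, and kept 2021 of the 3145 calls. Requiring an absolute log2 fold change of at least 0.58 left 448 and 315, and of at least 1 left 80 and 36, because fewer genes reach it. Median-ratio scaling gave 1508 and 1460, and quantile normalization 1594 and 1607, a share of higher calls of 50.8% and 49.8% against 44.9%. Camera called 5 to 9 lists with 1 library left out, 5 with a filter at 5 FPKM, where 2 of the 8 lists had too few members, and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. Fry called 10. The estrogen-induced list had an adjusted p of 0.111 with an estimated correlation, and 0.000226 to 0.0157 in the other camera settings. Of 118 single genes followed, 99 were called, of which 80 kept the call in each setting that tested them and 19 lost it in at least 1. Over all 118 genes, 0 of 1866 values reversed with a call. The robust prior does not enter camera, and HOTAIRM1 has no value with a filter at 5 FPKM.

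With the replicate number as a block, 1913 genes were higher and 2542 lower, and the camera adjusted p of the estrogen-induced list was 0.00177. Camera called 6 lists, without the HOXA cluster (adjusted p = 0.0694) and the mesenchymal and basal markers (adjusted p = 0.0503). The log2 fold change of HOTAIRM1, -1.61, cannot change with the block, because each group has 1 sample of each number. Its limma adjusted p without the expression filter was 0.0198. Deviations from the group means correlated at 0.25, 0.31 and -0.02 between samples of the same number. Replicates 1 and 2 of siControl correlated best with the siHOTAIRM1 sample of their own number, but siControl replicate 3 with siHOTAIRM1 replicate 1. The numbers are therefore not taken to pair the samples, though an effect shared by samples of the same number is not excluded.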

Other observations

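The tests of S phase, of the control siRNA, of ESR1 and of the estrogen-repressed genes were chosen after the results they bear on were seen, and the lists of cilium, TGF-beta and NRF2 genes after the largest changes were seen, leaving out the genes that prompted them. Of 49 tested cilium assembly genes, which build the cell's antenna-like projection, 13 fell and 1 rose, with a median log2 fold change of -0.20. IFT43 fell from 40.5 ± 1.34 to 27.4 ± 0.56 FPKM (SD, n = 3), BBS5 from 4.87 ± 0.537 to 2.5 ± 0.127 and TTC8 from 23.2 ± 3.02 to 14.5 ± 0.441, all chosen after their values were seen. Camera called the list lower (adjusted p = 5.11e-05 over the 3 added lists, and adjusted p = 0.138 with an estimated correlation). Of 15 TGF-beta targets 5 rose and 1 fell, and camera called the list higher (adjusted p = 0.00236, and adjusted p = 0.0837 with an estimated correlation). TGFB1 rose from 7.91 ± 0.823 to 14 ± 0.557, PMEPA1 from 37.1 ± 1.63 to 51.6 ± 0.663 and ID1 from 89.2 ± 1.63 to 124 ± 8, all chosen after their values were seen. Of 20 NRF2 targets 2 rose and 3 fell, and the list was not called (camera adjusted p = 0.428). The bootstrap interval of its median was -0.01 to 0.07, below the 0.1 set in advance. Bootstrap intervals here and below resampled the genes of a list, not the samples, so they leave out the spread between samples.

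Outside the fixed list, 31 other genes of the replication-dependent histone clusters were tested, and 17 of them fell and 0 rose (median log2 fold change -0.45, 95% bootstrap interval -0.62 to -0.34). Near-identical histone genes may share reads, so these genes are not independent of each other or of the fixed list. The fall of the histone genes was set against 4 explanations, each by whether other genes moved by at least 50% of the histone median, that is by -0.21. With fewer cells in S phase, the G1/S genes were predicted to fall at least 50% as much as the histone genes. They did not, with a median of -0.01 (95% bootstrap interval -0.05 to 0.08), above that bound. This argues against fewer cells in S phase only as far as these genes follow the share of such cells. How far they do was not measured, so this explanation stays open. A loss of short transcripts stays open. The 65 respiratory chain subunit genes set against it had a median of -0.15 (-0.19 to -0.09), above the bound set in advance, but 0 of them had a transcript length, so the test is void. Less capture of RNA without a poly(A) tail stays open too, since only 7 such RNAs were measured (median 0.20, interval -1.23 to 0.62), and so does a loss of all histone transcripts, where the 9 replication-independent histone genes had a median of -0.17 (-0.60 to -0.09) and H1F0, chosen after its value was seen, fell from 209 ± 9.3 to 137 ± 1.49 FPKM.

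The fall of the interferon-response list did not rest on a single library. In the 6 fits without 1 library the highest camera adjusted p was 2.98e-06. A response to the control siRNA in the siControl cells may account for it as well as the knockdown. With 0 untransfected samples these cannot be told apart.

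The rise of the estrogen-induced list did not rest on a single library either, with a highest camera adjusted p of 0.0157 in the 6 fits without 1 library. More ESR1 mRNA stays open, since the 95% interval of its log2 fold change, -0.12 to 0.20, holds both 0 and the median of the 56 members, 0.09. Whether estrogen signalling as a whole was higher stays open too, because the set tests differed on the estrogen-repressed list. Camera, the test set for this question, did not call it (adjusted p = 0.14), while fry did (adjusted p = 0.0119). Of the 10 splits of the 6 samples into groups of 3, 3 gave a camera p at least as small as the real 0.000271, the real one included, and the smallest of the others was 5.23e-05.

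For the counts, 10 splits are too few for a share under 0.05. The real split called 3145 genes and the highest of the others 1, so 1 split reached the real value. The real split called 8 lists and the highest of the others 5, so 1 split reached that value too, and camera with the preset correlation called several lists in splits with at most 1 called gene.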
